A study of Zea mays with 4 samples.

How the data were processed

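DAP-seq was carried out with 4 maize factors and genomic DNA of B73 leaf at 14 DAG, per the labels' protocols, with 1 library per factor. The groups are the factor names in the sample titles. The names inside the deposited file names differ from the titles, and the titles were followed through GEO's own assignment of files to samples. Reads were trimmed with Trimmomatic 0.39 and aligned with Bowtie2 2.4.1, per the submitters' processing notes. The peak caller, its settings, the control library and the genome build are not given in the sources used here. Peaks were listed for each library separately, and the deposited file names point to the removal of blacklisted regions, which can take out strong peaks as well as weak ones.

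Each deposited list has 10 columns in the narrowPeak layout. Every peak is 201 bp wide with its summit 100 bp after the start, so no information on peak width is kept. The authors' score per peak runs from 100 upward and is nearly a linear function of the signal (Pearson correlation 0.991 or above across the peaks of each list). The authors' signal is a non-negative value per peak whose scale is not stated, and it was used only to describe peaks within a list. The deposited −log10 p-value and −log10 q-value are given per peak, with a lowest −log10 q of 3 in every list and a cap at 999 reached by 16 THX20 peaks. Read numbers and library depth are unknown, so the precision of a single peak could not be judged. All intervals cover counting error of peaks only, and neighbouring peaks are not independent.

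Peaks were ranked by −log10 p, then by signal, since the score has many ties. Peaks overlapped when they shared at least 1 bp (summits at most 200 bp apart). For each of the 6 pairs, the shorter list was placed 100 times at random positions of the same chromosomes and contigs, from position 1 to the last peak end of any list, and an overlap was called above or below random when it lay outside the range of these placements. This is a description of these lists, without a p-value. Placement used every position in that span, so sequence where reads cannot be aligned and blacklisted regions were not left out. The lists share mappability and DNA methylation, so an excess over random is not read as binding together. Sites of all factors were regions formed by joining overlapping peaks. Profiles along chromosomes used the 10 chromosomes, and the analysis of bins used full bins of 1 Mb. Shares have 95% Wilson intervals, and ratios of medians and correlations have bootstrap intervals from 1000 resamples. Calculations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The overlap procedure was tested on simulated data: independent lists gave a fold of 1.03, and 5040 overlaps were recovered above random where 5000 had been planted.

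Before the data were examined, the tests, the alternatives and the rule for named sites were fixed. Without a matching annotation the rule names the 5 highest scoring peaks per factor and the 5 regions of all 4 factors with the best mean rank within their lists. The alternatives were the stronger 50% of each list, merged peaks, an overlap of over 50% of both peaks (with 201 bp peaks the same criterion as summits within 100 bp), equal numbers of strongest peaks, shifts of 10 to 100 kb in place of random placement, and bins of 5 Mb. The score had been named as the measure for ranking and for comparing shared with single-factor sites; because it takes few distinct values, −log10 p was used for ranking and the signal for that comparison. Rotation of whole lists and ranking by signal were added after seeing the data. The strength classes, the distances within and between lists, the central over outer contrast, the fullest bins, the contigs and the ranks inferred from q were also chosen after the data had been seen, and a first look with 5 random placements per pair came before the main run. A preferred neighbour distance is one between 15 and 1000 bp found at least 20 times, over 2 times and over 4 standard deviations (Poisson) above the mean of 20 distances around it. Between lists the same criteria were applied to distances from 1 to 300 bp, without regard to which summit came first, and the shortest distances were set against fewer than 20 around them.

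Planned comparisons of peaks with genes, promoters, gene lists and sequence motifs were left out, because no genome was used here. A gene table of the assembly Zm-B73-REFERENCE-NAM-5.0 was at hand, but its coordinates differ from those of the lists: on 9 of 10 chromosomes the last peak came 1.17 to 7.25 Mb before the last gene, and on chromosome 2 peaks ran 0.935 Mb past it. None of the 4 factor identifiers was listed in that table. Positions are given as in the deposited lists, counted from 1, without a build name, and no gene or exon is assigned to a site.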

Results

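The binding of 4 maize transcription factors to naked genomic DNA was measured by DNA affinity purification sequencing (DAP-seq). In this assay a tagged protein made in a cell-free extract is held on beads, a genomic DNA library is passed over it, and the DNA that stays bound is sequenced. The factors were C3H23 (Zm00001d008323), CPP2 (Zm00001d031008), OBF4 (Zm00001d012553) and THX20 (Zm00001d017420). By their names, C3H23 belongs to the CCCH zinc finger proteins, CPP2 to the cysteine-rich CPP family, OBF4 to the ocs-element binding factors of the bZIP class, and THX20 to the trihelix proteins. The submitters' design describes them as factors downstream of ZmNAC128 and ZmNAC130, which are NAC regulators of storage reserve synthesis in the maize endosperm. The DNA came from leaves of the inbred line B73 at 14 DAG, so the sites describe what each protein can bind in purified DNA, not what it occupies in endosperm. Each factor had 1 library, so no difference between factors has a replicate check and none is given a p-value. The number of reads behind each list is unknown.

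The number of peaks listed for each factor was described first. CPP2 had the most peaks, 165420, followed by THX20 with 105867, C3H23 with 76032 and OBF4 with 51187. The longest list was 3.23 times as long as the shortest. Every peak was 201 bp wide, so the lists differed in number and spacing but not in peak width. CPP2 peaks covered 31.4 Mb, THX20 peaks 20.2 Mb, C3H23 peaks 15.1 Mb and OBF4 peaks 10.2 Mb, each base counted once per list. On the 10 chromosomes this was 1.48% of the sequence for CPP2, 0.947% for THX20, 0.710% for C3H23 and 0.478% for OBF4. Because read depth is unknown, the lengths of the lists are not a measure of how permissive each factor is.

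The strength of single sites was taken from the authors' own signal and p-value per peak, which rank peaks within a list. The strongest THX20 peak lay on chromosome 3 from 180885880 to 180886080 and had a signal of 2849.2. The leading 5 THX20 peaks were all at the cap of the p-value and are ordered by signal alone. Its next strongest peaks were on chromosome 2 from 220675206 to 220675406 (signal 2466.3), chromosome 1 from 297291823 to 297292023 (2070.6), chromosome 7 from 68595078 to 68595278 (1893.1) and chromosome 10 from 86757655 to 86757855 (1547.3). The strongest OBF4 peaks were on chromosome 3 from 88772195 to 88772395 (signal 924.6), chromosome 7 from 101448037 to 101448237 (907.5), chromosome 9 from 118472680 to 118472880 (716.6), chromosome 3 from 74395855 to 74396055 (684.1) and chromosome 9 from 59774604 to 59774804 (637.8). None of these 10 peaks overlapped a peak of another factor. The strongest CPP2 peaks were on chromosome 1 from 285338079 to 285338279 (signal 764.1), chromosome 9 from 106166858 to 106167058 (759), chromosome 4 from 44115355 to 44115555 (638.7), chromosome 4 from 3537658 to 3537858 (582.2) and chromosome 7 from 8461644 to 8461844 (587.9). The 1st and 3rd of these overlapped C3H23 peaks. The strongest C3H23 peaks were on chromosome 2 from 216997978 to 216998178 (signal 657), chromosome 4 from 183175869 to 183176069 (652), chromosome 8 from 147358196 to 147358396 (633), chromosome 7 from 128897563 to 128897763 (607.6) and chromosome 4 from 236068414 to 236068614 (572). The 3rd and 4th of these overlapped CPP2 peaks and the 5th an OBF4 peak. The median signal was 41 for CPP2, 36 for C3H23, 32 for THX20 and 30.8 for OBF4, on scales that are not comparable between libraries.

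The lists were then compared to see which factors bind the same places. Most sites belonged to a single factor. After overlapping peaks of all lists were joined, 333903 regions were left, of which 93.9% held peaks of 1 factor, 5.80% of 2 factors and 0.309% of 3 factors. C3H23 shared the most: 21.2% of its peaks (95% Wilson interval 20.9 to 21.5%) overlapped a peak of at least 1 other factor. This share was 11.1% (10.9 to 11.3%) for THX20, 8.17% (7.93 to 8.41%) for OBF4 and 8.12% (7.99 to 8.25%) for CPP2. Of the 1049 regions bound by 3 or 4 factors, 1010 (96.3%) included C3H23, against 66 to 78.9% (mean 73.3%) when all lists were placed at random. Regions of exactly 3 factors with C3H23 exceeded random placement: 628 with CPP2 and THX20 (51 to 90 at random), 220 with CPP2 and OBF4 (21 to 48) and 144 with OBF4 and THX20 (11 to 32). The 39 regions of CPP2, OBF4 and THX20 without C3H23 lay within the random range (32 to 58). Placing all lists at random also undoes the overlap between pairs of lists. The comparison therefore does not test for sites of 3 or 4 factors beyond what the pair overlaps give. The joined peaks of a region need not all overlap each other. The intervals cover counting error only, and list lengths also set the shares.

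**Figure D1:**
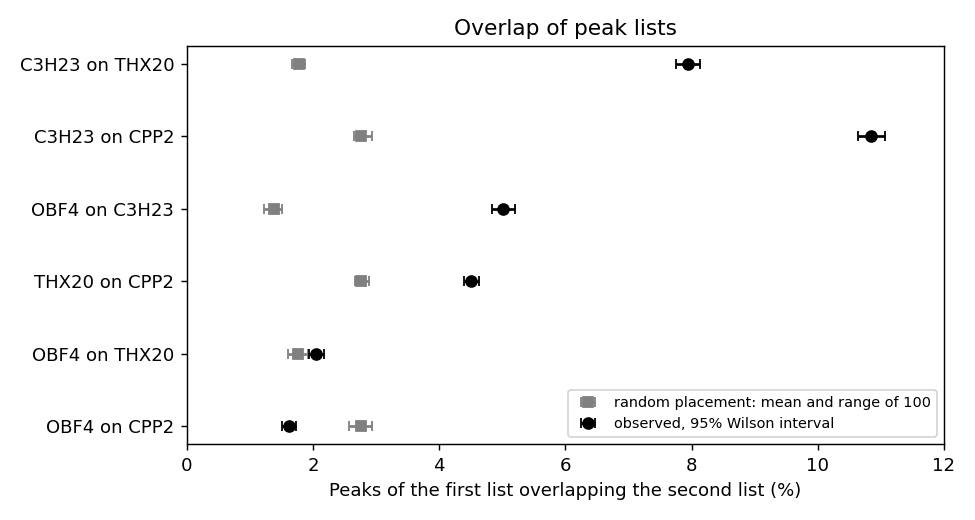
Share of the peaks of the first-named (shorter) list that overlap the second list by at least 1 bp, in percent, for the 6 pairs of factors. Black points are observed shares with 95% Wilson intervals and grey squares the mean and range of 100 random placements; the pairs with C3H23 lie far to the right of random placement and OBF4 on CPP2 lies to its left.

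To take list length into account, each overlap was set against 100 random placements of the shorter list on the same chromosomes and contigs. C3H23 overlapped every other factor more often than random placement. Of its peaks, 8249 (10.8%) overlapped CPP2, against 2012 to 2229 at random, 3.94 times the random mean; with the stronger 50% of each list by signal this fell to 2.59-fold. With THX20, 6040 C3H23 peaks (7.94%) overlapped, against 1263 to 1421, a 4.49-fold excess. With OBF4, 2567 OBF4 peaks (5.01%) overlapped C3H23, against 627 to 773, a 3.64-fold excess. The pairs without C3H23 behaved differently. OBF4 and CPP2 overlapped less often than random placement: 829 OBF4 peaks (1.62%, 1.51 to 1.73%) overlapped CPP2, against 1314 to 1502, 0.588 times the random mean. OBF4 and THX20 shared 1050 OBF4 peaks, against 824 to 979, a 1.16-fold excess that lay within the random range when only the stronger 50% of each list was used (1.04-fold). THX20 and CPP2 shared 4775 THX20 peaks, against 2829 to 3062, a 1.63-fold excess. That excess was gone in the stronger 50% of each list (0.966-fold by p-value, within the random range) and turned below random (0.730-fold, 340 peaks against 398 to 521) when the 51187 strongest peaks of every list were compared. Joined regions without C3H23 gave lower values: 867 held OBF4 and THX20 alone, against 885 to 1007 at random (0.912-fold, below the range), and 3541 held THX20 and CPP2 alone, against 3002 to 3279 (1.14-fold). Grouped peaks join into fewer regions than placed ones, and single-factor regions were also below random (0.810-fold to 0.959-fold). The excess of THX20 with CPP2 and with OBF4 was not confined to overlapping peaks. THX20 and CPP2 summits from 500 to under 1000 bp apart stood at 2.09 times a uniform expectation. OBF4 and THX20 summits from 300 to under 500 bp apart stood at 1.37 times.

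To follow this dependence on peak strength, each list was divided into 10 equal strength classes by p-value. CPP2 peaks overlapped THX20 0.531 times as often as random placement in the strongest class (156 peaks against 259 to 333) and 2.54 times as often in the weakest (745 against 249 to 338). THX20 peaks overlapped CPP2 more often than random placement in all 10 classes, between 1.48-fold and 1.75-fold, so the change was seen across the CPP2 classes and not across the THX20 classes. CPP2 peaks overlapped OBF4 less often than random placement in all 10 classes, 0.419-fold in the strongest and 0.605-fold in the weakest. The strongest class of OBF4 peaks overlapped CPP2 within the random range (142 peaks against 118 to 171), while the other 9 classes lay below it. Their folds were 0.749 in the 2nd class, 0.457 and 0.445 in the 3rd and 4th, and 0.597 and 0.576 in the 9th and 10th. The OBF4 overlap with C3H23 was 1.58-fold in the strongest OBF4 class and 4.49-fold in the weakest, whereas among C3H23 peaks it was 5.58-fold in the strongest class and 2.50-fold in the weakest. By contrast, THX20 peaks overlapped C3H23 between 3.86-fold and 5.11-fold in all 10 classes. By the authors' signal, the median of peaks shared with any other list was 0.794 times that of single-factor peaks for CPP2 (bootstrap 95% interval 0.786 to 0.816) and 0.903 times for OBF4 (0.877 to 0.903), against 0.997 times for C3H23 (0.973 to 1) and 1 for THX20 (0.994 to 1.02).

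**Figure D2:**
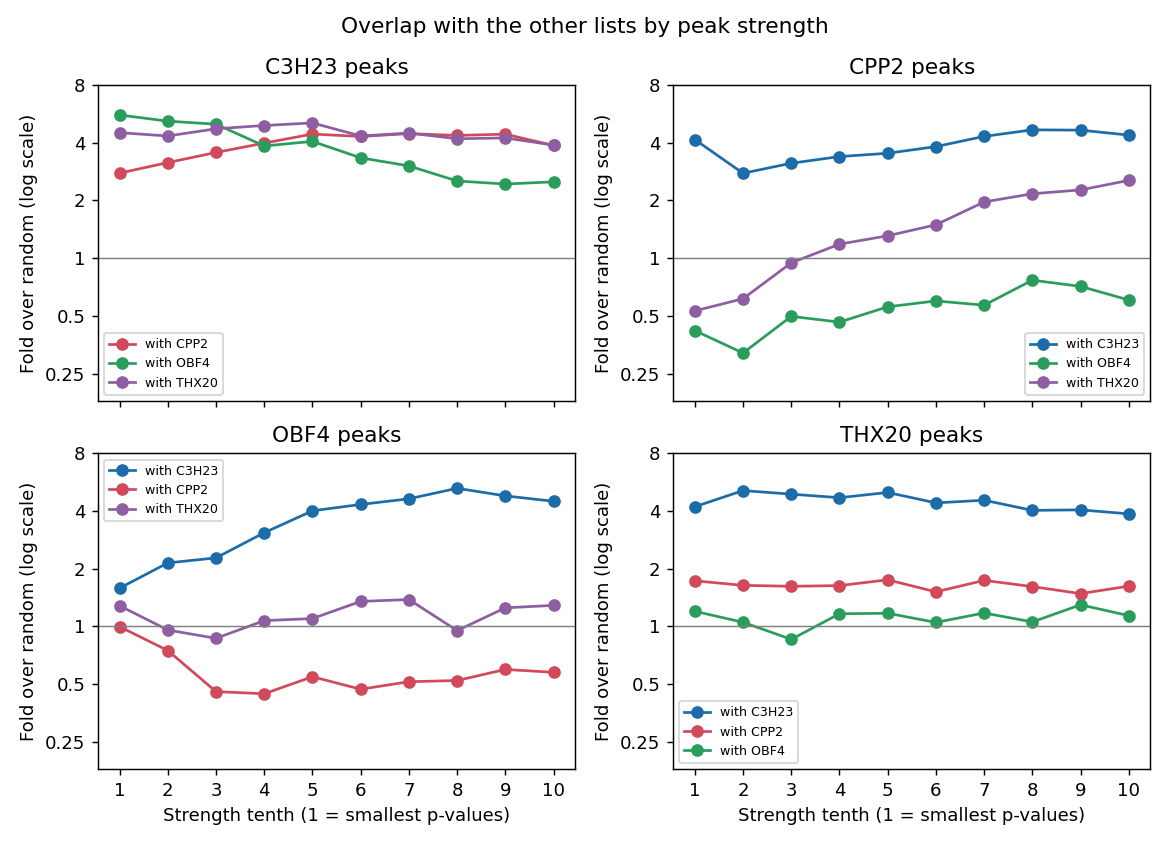
Overlap of each factor's peaks with the other lists as fold over the mean of 100 random placements (vertical axis, log scale), by strength class of the peaks (horizontal axis, 1 = the 10% with the smallest p-values, 10 = the weakest). Each line is a partner list; CPP2 peaks move from 0.531-fold to 2.54-fold overlap with THX20 as they weaken, while THX20 peaks stay between 3.86-fold and 5.11-fold with C3H23.

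Sites of all 4 factors were rare. There were 18 such regions, against 0 to 4 (mean 1.33) when all lists were placed at random, and they lay on chromosomes 1, 2, 3, 4, 7, 8 and 9. Such placement undoes the pair overlaps as well, so this excess does not show sites of all 4 factors beyond them. The region with the best mean rank lay on chromosome 4 from 179431288 to 179431715; its best C3H23 peak was within the top 0.214% of that list and its best THX20 peak at 80.3%. The next was on chromosome 4 from 14850566 to 14851395, with C3H23 at 1.36% and THX20 at 2.86% of their lists but CPP2 at 58.0% and OBF4 at 71.2%. The others of the leading 5 were on chromosome 8 from 78660681 to 78661087, chromosome 1 from 92683438 to 92683877 and chromosome 4 from 140996885 to 140997202. In 2 places the 4 summits lay within 100 bp. No region of all 4 factors was left when only the stronger 50% of each list by p-value was used, where random placement gave a mean of 0.05, so no direction can be read at that list length.

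**Figure D3:**
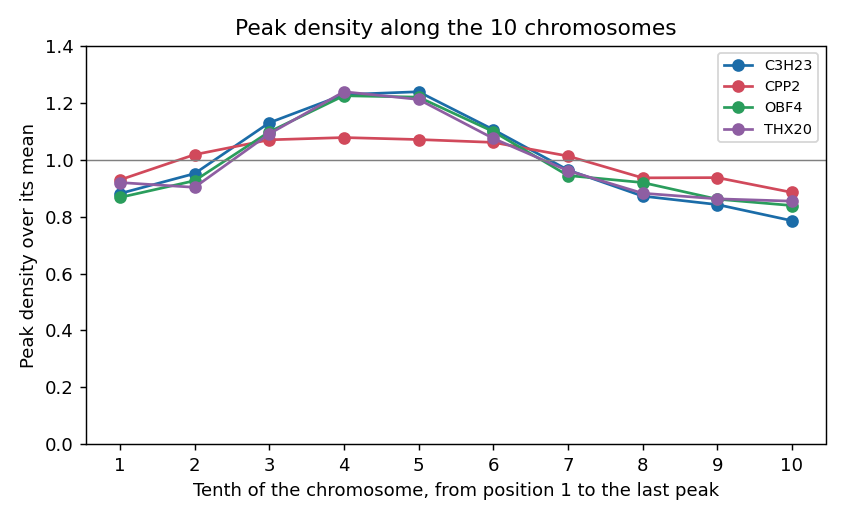
Peak density in each 10% of chromosome length, from position 1 to the last peak, over the mean density of the list (vertical axis, no unit), summed over the 10 chromosomes. All 4 factors are densest between the 3rd and 6th classes, and the CPP2 profile is the flattest.

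The distribution of sites along the chromosomes was described next. Peaks of all 4 factors were denser in the middle of chromosomes than at their ends. C3H23 had 41.9 peaks per Mb in the central 20% of chromosome length and 29.8 per Mb in the outermost 10% at either end, a ratio of 1.41 (95% counting interval 1.38 to 1.44). The ratio was 1.36 (1.32 to 1.397) for OBF4, 1.29 (1.26 to 1.31) for THX20 and 1.17 (1.16 to 1.19) for CPP2. It was above 1 on 10 of 10 chromosomes for every factor. Whole chromosomes differed little: the densest exceeded the sparsest by 1.13 times for C3H23 and OBF4, 1.10 times for THX20 and 1.06 times for CPP2. Chromosome 7 was the densest for C3H23, CPP2 and OBF4 (37.7, 80.2 and 25.7 peaks per Mb), and chromosome 4 for THX20 (52.2). Across 2101 bins of 1 Mb, which are not independent replicates, peak numbers rose together in all 6 pairs, from a Spearman correlation of 0.346 for OBF4 with CPP2 (Pearson 0.365) to 0.573 for C3H23 with THX20 (Pearson 0.604). These correlations depended on the bins and peaks used: they ran from 0.640 to 0.780 in bins of 5 Mb and from 0.175 to 0.449 in the stronger 50% of each list. The bin from 93000001 to 94000000 on chromosome 4 was the fullest for both OBF4 (50 peaks, median of all bins 23) and THX20 (115 peaks, median 48).

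Sites of a factor also stood in groups, to a different degree in each list. Of the CPP2 peaks, 41.9% had another CPP2 peak within 1 kb, and for THX20 this share was 41.6%. It was 28.6% for C3H23 and 12.6% for OBF4. Lists with more peaks have closer neighbours by chance, so these shares follow list length in part. They do not rank the factors by grouping, since the shares under random placement were not computed. Within groups, neighbouring summits stood at preferred distances. In CPP2 the most frequent was 54 bp, found 586 times against a mean of 72 at the distances around it, followed by 155 bp (519 times) and 125 bp (507 times). In THX20 it was 153 bp (359 times against 94.5), followed by 182 bp (308 times). OBF4 had 82 bp (37 times against 6.5) and C3H23 269 bp (65 times against 29.2).

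**Figure D4:**
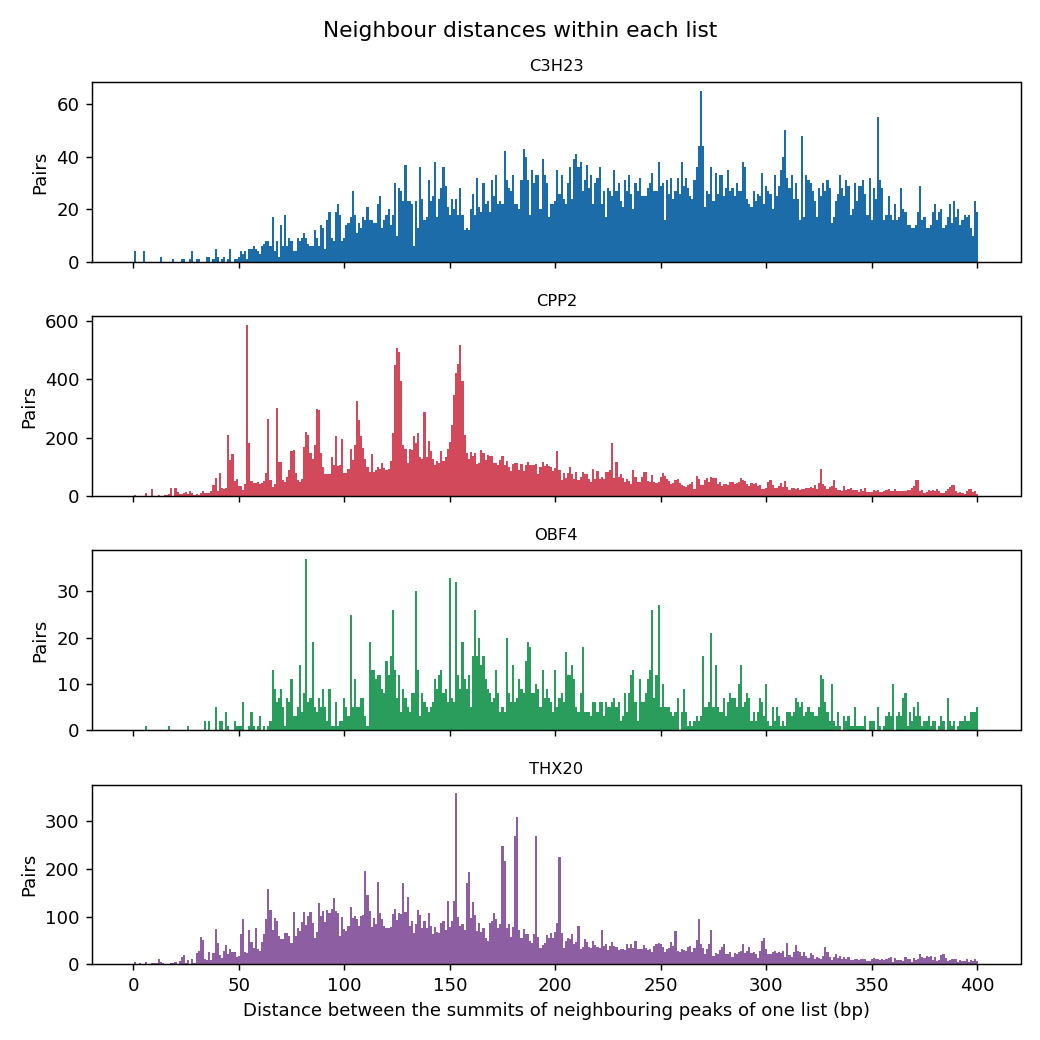
Number of neighbouring peak pairs (vertical axis, own scale for each list) by the distance between their summits in bp (horizontal axis, up to 400 bp), for C3H23, CPP2, OBF4 and THX20. CPP2 shows narrow maxima at 54, 125 and 155 bp and THX20 at 153 and 182 bp, while the C3H23 distribution is broad.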

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

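All 4 lists also held peaks on contigs not placed on a chromosome, which the comparison along chromosomes did not use; no control library was used here to set them against. There were 805 such peaks for C3H23, 1658 for CPP2, 609 for OBF4 and 1072 for THX20, on 180 contigs in all. Per Mb of contig, OBF4 had 28.6 peaks against 24.0 on the chromosomes, C3H23 37.8 against 35.7, THX20 50.3 against 49.8 and CPP2 77.82 against 77.75. Contig length was counted up to the last peak, over contigs with a peak only (21.3 Mb), which raises the contig densities. The same contig, number 150, held the most peaks in every list (152 for CPP2, 89 for THX20, 86 for C3H23 and 70 for OBF4). Its length was not taken into account.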

How the results depend on the processing

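No paired analysis was possible because each factor had 1 library, and for the same reason no replicate could be left out. The settings foreseen for genes, motifs and gene lists were not run, because no matching genome was used here. Rotation of whole lists and ranking by signal were chosen after seeing the data. The 3 C3H23 overlaps stayed above random placement (2.59-fold to 5.21-fold) and the OBF4 and CPP2 overlap below it (0.409-fold to 0.586-fold) under all 6 alternatives. THX20 and CPP2 turned to 0.966-fold with the stronger 50% by p-value, 0.962-fold by signal (both within the random range) and 0.730-fold, below it, with equal numbers of strongest peaks. OBF4 and THX20 fell within the random range at 1.04-fold with the stronger 50% by p-value and 1.07-fold by signal. Regions of all 4 factors numbered 2 with summits within 100 bp, and 0 with the stronger 50% by p-value or by signal and with equal numbers of strongest peaks, where fewer than 1 was expected at random; that these zeros show no direction was settled after they were seen, as was reading the C3H23 signal ratio, whose interval reaches 1, as having none. By construction the stronger 50% held 38016 C3H23, 82710 CPP2, 25593 OBF4 and 52933 THX20 peaks. With over 50% of both peaks overlapping, shared over single-factor median signal was 1.03 for C3H23, 0.749 for CPP2 and 0.871 for OBF4. The central over outer density ratio in the stronger 50% was 1.60 for C3H23, 1.13 for CPP2 and 1.45 for OBF4. In 5 Mb bins the correlations rose to 0.727 (C3H23 and CPP2), 0.769 (C3H23 and OBF4), 0.780 (C3H23 and THX20), 0.640 (OBF4 and CPP2), 0.644 (THX20 and CPP2) and 0.732 (OBF4 and THX20). In the stronger 50% they were 0.277, 0.449, 0.430, 0.175, 0.211 and 0.326 in the same order. Shorter lists follow from the construction of the stricter settings; the cause of the other changes was not tested. The unknown depth limits every count of peaks.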

Other observations

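Summits of different factors also stood at preferred distances from each other. C3H23 and THX20 summits were 286 bp apart 152 times, against a mean of 27.3 at the distances around it, and 129 bp apart 134 times against 33.6. OBF4 and THX20 summits were 81 bp apart 42 times against 6.1, and C3H23 and OBF4 summits 12 bp apart 68 times against 22.7. Both signs of each distance were counted together. The C3H23 excess around OBF4 was steepest at close range, 5.59 times a uniform expectation below 50 bp and 2.86 times from 100 to under 200 bp. Around CPP2 it was 3.70 times below 50 bp and 3.96 times from 100 to under 200 bp. From 200 to under 300 bp the excess was 2.73 times around OBF4 and 2.925 times around CPP2. From 300 to under 500 bp it was 2.46 times around OBF4 and 1.70 times around CPP2. The OBF4 deficit around CPP2 was deepest below 100 bp (0.389 times below 50 bp, 0.393 times from 50 to 99 bp) and did not fade steadily beyond that: 0.687 times from 100 to under 200 bp, 0.839 times from 200 to under 300 bp, 0.671 times from 300 to under 500 bp and 0.781 times from 500 to under 1000 bp. THX20 around CPP2 fell from 1.75 times below 50 bp to 1.275 times from 200 to under 300 bp. It then rose to 1.60 times from 300 to under 500 bp and 2.09 times from 500 to under 1000 bp. OBF4 around THX20 was 1.06 times below 50 bp, 1.42 times from 50 to 99 bp and 1.01 times from 100 to under 200 bp. Further out it was 1.20, 1.37 and 1.13 times over the same 3 ranges. For these pairs the overlap excess did not stand out from that of summits further apart.

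The ratio of p-value to q-value tells the rank at which a peak stood when q was computed, if q was a Benjamini-Hochberg value and the weakest listed peak kept its rank. If peaks ahead of the weakest peak were removed, its rank was larger than the list length used here. The ranks are therefore approximate, and removal makes them too low. On that reading the best listed C3H23 peak stood at rank 81.5, the best CPP2 peak at 56.1 and the best OBF4 peak at 23.9. Rounding of the C3H23 peak's own p and q alone gives 79.6 to 83.4, and rounding at the weakest peak widens this. The THX20 peak listed at rank 17, the best below the cap, stood at 96.5. The peaks listed at rank 100 stood at 372 for C3H23, 275 for CPP2, 141 for OBF4 and 473 for THX20, so that the strongest peaks named in the report were the strongest left in the lists.

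In the tests that follow, those of weak CPP2 peaks, of peak splitting and of the number of bins in OBF4 were chosen only after the result was seen; the shift that tests regional density was fixed beforehand, but the bounds it was read against were not. For weak OBF4 peaks the value met the bound set beforehand for that explanation, which was then worded as weak background peaks without naming a list; the narrower wording and its reading as open were settled after all values were seen. The first pattern is the overlap of C3H23 with every other factor. Differences in peak density over distances longer than the shift do not account for it as a whole. The smallest of the 3 C3H23 folds was 3.45 after peaks were shifted by 10 to 100 kb. The shift did not test density at shorter range. Beyond overlap, C3H23 summits still exceeded a uniform expectation. From 200 to under 300 bp, where only summits exactly 200 bp apart overlap, they stood at 2.925 times with CPP2, 3.89 with THX20 and 2.73 with OBF4. From 300 to under 500 bp the values were 1.70, 3.21 and 2.46 in the same order. From 500 to under 1000 bp they were 1.80 times with CPP2, 1.82 times with THX20 and 1.48 times with OBF4. Weak C3H23 peaks do not account for the overlap as a whole either. The strongest 10%, set against all peaks of each partner, kept at least a 2.75-fold excess. Groups of close peaks do not account for the overlap either. Peaks with no neighbour of their own list within 1 kb had at least a 3.49-fold excess. With CPP2, the excess was 2.78-fold in the strongest C3H23 class, 4.46-fold in the 7th and 3.87-fold in the weakest. Weak C3H23 peaks therefore remain open as a contributor to that pair. From the strongest to the weakest C3H23 class the excess fell with OBF4 (5.58-fold to 2.50-fold) and with THX20 (4.51-fold to 3.89-fold). Among OBF4 peaks the excess with C3H23 was only 1.58-fold in the strongest class, so weak OBF4 peaks remain open as a contributor to that pair. A preference of C3H23 for sequence that the others also bind and background DNA particular to its library both stay open, since no genome and no control library were used here. Mappability and DNA methylation shared by the lists stay open as well, since neither random placement nor the shift accounted for them.

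The second pattern is the overlap of OBF4 and CPP2 below random placement. Density differences over distances longer than the shift do not account for it (0.572-fold after the shift). Neither do groups of close peaks (0.648-fold among isolated peaks) or weak CPP2 peaks (0.419-fold for the strongest CPP2 class). Density at shorter range was not tested by the shift, and the deficit reached beyond overlap (0.781 times from 500 to under 1000 bp). The deficit was missing where the strongest 10% of OBF4 peaks met the stronger 50% of CPP2 peaks (1.04-fold, 77 peaks against 51 to 102), but the stronger 50% of both lists still gave 0.576-fold, and with all CPP2 peaks the 3rd and 4th OBF4 classes lay lower (0.457 and 0.445) than the 9th and 10th (0.597 and 0.576). Weak OBF4 peaks as the source are therefore left open, although the first value alone met what had been predicted for them. A difference in base composition between the sequences that the 2 proteins bind is a candidate explanation that needs the genome and stays untested.

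The third pattern is the set of preferred distances between neighbouring peaks of a list. Location was checked only for the most frequent distance of each list. A tandem array at a single place does not account for that distance in C3H23, CPP2 and THX20. At most 12.3% of its pairs (upper Wilson limit 22.4%) lay in the 5 fullest bins of 1 Mb. In OBF4 that share was 13.5% with an upper limit of 28.0%, too wide to decide, but its 37 pairs lay in 37 different bins, where an array holding 50% of them in 5 bins allows at most 23. Splitting of wide peaks by the caller stays open: 20.9% of the 67 preferred distances (upper Wilson limit 32.1%) were preferred in another list, 95% of random draws gave 2.99 to 22.4%, and splitting that differs between libraries would leave few shared distances. Copies of dispersed repeats with binding sites at fixed spacing are a candidate explanation that was not tested, since no repeat annotation was used here.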
